A study of Mus musculus with 4 samples.

How the data were processed

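RNA sequencing libraries of regulatory T cells from epididymal white adipose tissue (eWAT) and spleen of C57BL/6 mice aged 12 to 13 months were used, 4 libraries in all, with 1 for each combination of tissue and genotype (WT or PPARg-2KR). Groups were taken from the sample labels. Whether each library came from 1 animal or from pooled animals, and how the cells were gated in the sort, is not stated in the sources used here.

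The deposited read counts are whole numbers for each gene symbol, made by the authors' sequencing facility without scaling. Per the deposited readme, poly-A selected TruSeq libraries were sequenced with 100 bp reads, converted with bcl2fastq 1.8.4 and aligned to mm9 with Tophat 2.1.0, allowing 4 mismatches and up to 10 multiple hits. The counting tool, its use of strand and its treatment of reads with several hits are not given in the sources used here, so genes with overlapping or near-identical copies are uncertain. The labels name a second build, mm8, beside mm9. The deposited FPKM values were made by the authors with Cufflinks 2.0.2, per gene locus and per transcript, and are scaled for length and for mapped fragments. Gene counts were the main measurement. FPKM served for alternatives and for the transcripts of Pparg and Foxp3.

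Count totals were 13250590 (WT spleen), 15993889 (2KR spleen), 11186660 (WT eWAT) and 8315569 (2KR eWAT), and 19463, 18540, 21271 and 21775 of 23284 symbols had at least 1 read. Ribosomal Rn45s took 0.569, 0.512, 0.303 and 0.247% of the reads in that order and stayed in the totals. Trimmed mean of M-values (TMM) factors were 0.934, 0.953, 0.968 and 1.159.

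Tests and scaling used R 4.3.3 with edgeR 4.0.16, and alternatives used DESeq2 1.42.0 and limma 3.58.1. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. The tissue effect was tested with edgeR's quasi-likelihood test on 2 eWAT against 2 spleen libraries, for 16488 genes that passed the edgeR expression filter, with Benjamini-Hochberg adjustment and a threshold of 0.05. The p-values measure only the spread between these libraries, which includes the genotype difference. The biological coefficient of variation was 0.221. A genotype effect common to both tissues was tested with tissue as a further term and 1 residual degree of freedom (coefficient of variation 0.234). Genotype differences within a tissue, and the difference between tissues, were given as values without a p-value: log2 ratios of TMM-scaled CPM with a prior count of 2, over 12364 genes at 5 CPM or more in at least 1 library. Exact conditional binomial intervals of 95% on their reads cover counting error only. A gene with 0 reads was given a floor of 3 reads for a lower bound on its fold.

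There were 26 gene lists with 533 members found in the files, fixed before the files were read. They cover fat Treg, lymphoid or resting Treg, Treg core, T cell identity, PPARG target and lipid handling, cholesterol synthesis, cell cycle, interferon response, immediate early and stress, NF-kB target, effector T helper, chemokine and adhesion receptor, glycolysis, ribosomal protein and oxidative phosphorylation genes. The others are markers of adipocytes, macrophages and monocytes, dendritic cells and antigen presentation, B cells, plasma cells, CD8 T and NK cells, innate lymphoid type 2 and mast cells, fibroblasts and mesothelium, endothelium, neutrophils and erythroid cells. For the tissue effect, members past the threshold were counted over all genes and again adjusted over the list alone. The percentile of a list's median tissue ratio among matched random lists is given for some lists. For genotype, each list's median log2 ratio was given with an order-statistic interval. Its percentile was taken among 10000 random lists matched on 10 bins of mean expression over the 4 libraries. The fat-high and fat-low signatures held the 200 genes with the highest and lowest mean tissue ratio.

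Genes were named by a fixed rule: anchor genes, up to 12 genes per direction for the tissue effect and for genotype in eWAT, up to 5 per direction for genotype in spleen and for the difference between tissues, up to 10 for the common genotype effect, and up to 4 members of a list. Ratios needed 10 CPM and 100 reads in 1 library. Symbols without a gene name were skipped by the rule, and some genes that it selects are not reported here. Named outside it, chosen after their values were seen, were AA467197, 1700061F12Rik and the list members Itgae, Penk, Batf, Ptger4, Il7r, Tcf7, Cd3e, Gzmb, Adipoq, Cd74, Gpr55, Junb, Cd83, Dgat1, Itgb7, Cd44 and Hmgcs1.

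The steps were tested on simulated data with a coefficient of variation of 0.2. In the tissue test 31 of 100 genes changed by a log2 of 1 and 98 of 100 changed by 2 were recovered, with 9 false calls, and in the genotype test 32 and 96, with 4 false calls. Of unshifted random lists 5% lay outside percentiles 2.5 to 97.5, and 97.5% of lists shifted by 0.5 lay above. The simulated ratios did not depend on expression level, so this does not test the matching on level or lists that differ between tissues. Alternatives covered scaling, prior counts, filters, size thresholds, FPKM in place of counts, other test packages, signature sizes and leaving out each library. Centring on genes of at least 100 CPM, signatures at 50 CPM or more and counts at 20 CPM or more were added after the data were seen.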

Results

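Gene expression was measured by RNA sequencing in regulatory T cells (Treg cells, the FOXP3-expressing T cells that restrain immune responses) sorted from aged C57BL/6 mice of 12 to 13 months. The cells came from epididymal white adipose tissue (eWAT, a visceral fat depot) or from spleen, which served as the control tissue. The mice were wild type (WT) or carried PPARg-2KR, a changed form of PPARG, the nuclear receptor that fat Treg cells express at a high level. There were 4 libraries, 1 for each combination of tissue and genotype, named here WT spleen, 2KR spleen, WT eWAT and 2KR eWAT. Read counts summed to 13250590 in WT spleen, 15993889 in 2KR spleen, 11186660 in WT eWAT and 8315569 in 2KR eWAT, over 23284 gene symbols. A gene with 0 reads in a library is limited by 3 reads to 0.242, 0.197, 0.277 and 0.313 CPM (counts scaled to TMM-adjusted library size) in the same order. With 1 library per group there was no replicate check on any genotype difference within a tissue. Intervals given for those differences cover counting error only, since reads are not independent molecules and no animal-to-animal spread is included.

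The targeted gene, Pparg (chromosome 6, 115311239 to 115440419 in mm9), was measured in every library. Pparg stood at 5.74 CPM in WT spleen, 2.89 CPM in 2KR spleen, 129.8 CPM in WT eWAT and 64.2 CPM in 2KR eWAT. The log2 ratio of 2KR over WT was −1.01 in eWAT (95% exact interval −1.15 to −0.88) and −0.95 in spleen (−1.57 to −0.43). The knock-in alters the protein, so this level does not test the genotype labels. Foxp3, the lineage factor of Treg cells, stood at 1409, 1299, 1162 and 804 CPM in WT spleen, 2KR spleen, WT eWAT and 2KR eWAT.

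**Figure D1:**
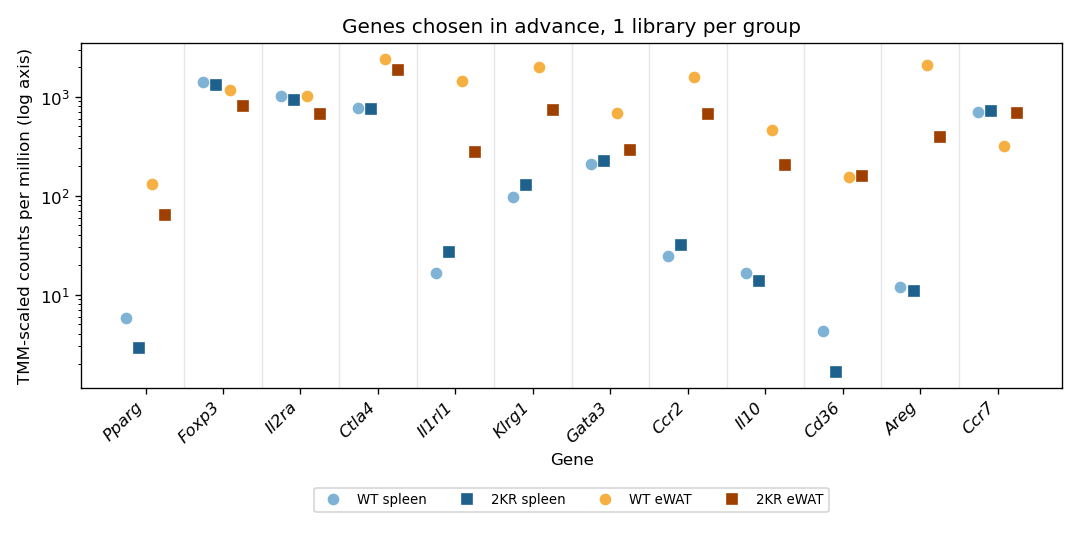
TMM-scaled CPM (vertical log axis) of 12 genes chosen before the data were examined, with 1 point for each of the 4 libraries and no error bars because each group has 1 library. Foxp3 lies between 804 and 1409 CPM in the 4 libraries, while Areg lies at 11.8 CPM in WT spleen, 10.8 CPM in 2KR spleen, 2072 CPM in WT eWAT and 387.5 CPM in 2KR eWAT.

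The first comparison asked which genes set fat Treg cells apart from spleen Treg cells, and used the 2 eWAT libraries against the 2 spleen libraries. Genes known for fat Treg cells were far higher in eWAT. Pparg was higher by 4.51 on the log2 scale (SE 0.37, edgeR adjusted p = 6.52e-07), Il1rl1, which encodes the IL-33 receptor ST2, by 5.29 (SE 0.59, adjusted p = 1.32e-05), and Areg, the growth factor amphiregulin, by 6.77 (SE 0.64, adjusted p = 2.63e-06). Ccr2, a chemokine receptor, was higher by 5.33 and Cd36, a fatty acid transporter, by 5.75. Of the 36 members of the list of known fat Treg genes, 27 rose in eWAT, 5 fell (Itgae, Penk, Batf and Ptger4 among them) and 4 did not pass, and the counts adjusted over the list alone were the same 27 and 5. In the list of lymphoid or resting Treg genes, 20 of 24 fell and 2 rose (Ccr9 and Il7r), with the same counts adjusted over the list alone. Tcf7, a transcription factor of resting T cells, fell by 2.82 and Id3 fell by 3.16. Ccr7, a lymph node homing receptor, had a log2 fold change of −0.51 (adjusted p = 0.168).

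Treg core genes were mixed across tissues. Of 22 members, 4 were higher, 6 were lower and 12 did not pass, both over all genes and adjusted over the list alone. Foxp3 had a log2 fold change of −0.46 (SE 0.27, adjusted p = 0.162) and Il2ra of −0.22 (SE 0.27, adjusted p = 0.513), whereas Ctla4, an inhibitory receptor, was higher in eWAT, at 776 and 749 CPM in WT and 2KR spleen and 2424 and 1881 CPM in WT and 2KR eWAT (edgeR adjusted p = 0.000798). The Foxp3 call changed with the method, with adjusted p = 0.0437 in DESeq2. Gpr83 was lower in eWAT, with a log2 fold change of −4.09, and so was Nt5e, the ectoenzyme CD73, at −2.08. Of 14 T cell identity genes, 10 were lower in eWAT and 4 did not pass (also adjusted over the list alone), with Cd3e at −1.03 and Lck at −1.24.

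Genes of activation and lipid handling differed in number between directions. Of 30 immediate early and stress genes, 17 were higher in eWAT and 5 lower, with Fosb up by 6.18 and Nr4a1 by 3.46. Of 22 NF-kB target genes, 12 were higher and 3 lower, and Nfkbid, a regulator of NF-kB signalling, was up by 2.68. Of 32 PPARG target and lipid handling genes, 14 were higher and 5 lower. Among them Fabp4, a fatty acid binding protein, was up by 7.75, and Plin2 and Hilpda, lipid droplet proteins, by 3.24 and 3.86. Each of these 3 counts was unchanged when adjusted over the list alone. The 28 interferon response genes included 19 lower and 2 higher members. Effector T helper genes gave 12 higher and 3 lower of 23, with Gzmb at 3.91 and Il5 at 5.16. Chemokine and adhesion receptor genes gave 13 higher and 7 lower of 28, with Cxcr6 at 4.69 and Cxcr5 at −3.49. Interferon, effector and receptor counts were also unchanged adjusted over the list alone. Some counts looked too low in these files, which makes the next lists uncertain. Gapdh, a glycolysis gene, stood at 8.97, 9.58, 16.3 and 14.7 CPM in WT spleen, 2KR spleen, WT eWAT and 2KR eWAT. Hmgcs1, a cholesterol synthesis gene, had 0 reads in each. The cause, such as the counting of genes with near-identical copies, was not tested. Cytosolic ribosomal protein genes were lower for 23 of 28 and higher for 0 (24 lower adjusted over the list alone), and oxidative phosphorylation genes were lower for 18 of 23 and higher for 1. Glycolysis genes gave 3 higher and 6 lower of 17 (5 lower adjusted over the list alone) and cholesterol synthesis genes 2 higher and 6 lower of 22. Cell cycle genes gave 1 higher and 6 lower of 26 (0 and 2 adjusted over the list alone). Among random lists matched on mean expression, the median tissue ratios of the glycolysis, cholesterol and cell cycle lists lay at percentiles 52.2, 56.4 and 44.3, so none stood out.

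Markers of several other cell types were higher in the eWAT libraries together with these groups. Over all genes tested, 5555 of 16488 were higher. All 18 fibroblast and mesothelial markers tested were higher in eWAT, as were 19 of 20 macrophage and monocyte markers, 13 of 14 dendritic cell and antigen presentation markers, 12 of 13 endothelial markers, 8 of 8 plasma cell markers and 9 of 9 innate lymphoid type 2 and mast cell markers. Of the adipocyte markers 7 of 8 tested were higher, yet Adipoq, the adiponectin gene, had 0 reads in WT eWAT and 11 in 2KR eWAT. B cell markers gave 7 higher and 3 lower of 16, CD8 T and NK cell markers 4 higher and 2 lower of 12, neutrophil markers 5 higher of 9 and erythroid markers 4 higher of 6. Each of these counts was the same adjusted over the list alone. Among random lists matched on mean expression, the median tissue ratio lay at percentile 90.0 for B cell markers and 65.2 for CD8 T and NK cell markers. It lay at 19.1 for neutrophil and 16.0 for erythroid markers, so these lists did not stand out from genes of like mean expression. Several of these genes were abundant. Cd74, the MHC class II invariant chain, was at 4510 CPM in WT eWAT and 8305 CPM in 2KR eWAT against 742 and 502 CPM in WT and 2KR spleen, and Lyz2 was at 1017 and 1215 CPM against 19.8 and 24.2 CPM.

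In all, 5555 genes were higher and 3832 lower in eWAT of 16488 tested, and 7101 did not pass (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Of these, 5213 and 1454 differed by at least 2-fold. Among the 7470 genes with a mean level of at least 20 CPM the majority turned. There 360 had a mean tissue log2 ratio of at least 1 and 1019 of −1 or lower, counted without a test. Olfactory and vomeronasal receptor genes took 3483 and 2383 reads in WT and 2KR spleen, and 6808 and 12210 in WT and 2KR eWAT. T cells have little reason to express these genes, so some rises among weakly expressed genes may be background reads, which was not tested. The strongest rises included genes with 0 reads in both spleen libraries, for which a floor of 3 reads over both libraries gives a lower bound: Cav1, a caveolar membrane protein, was at least 736-fold higher, Wnt11 at least 259-fold and Ccl11, the chemokine eotaxin, at least 122-fold. Atf3, a stress-induced transcription factor, was higher by 9.36 on the log2 scale (SE 0.69), Ccl22 by 9.69, and the myeloid lectin genes Clec10a by 9.48 and Mgl2 by 9.45. Of the genes with the strongest falls, Dtx1, a Notch pathway ubiquitin ligase, had −5.85 (SE 0.25, adjusted p = 3.87e-09), Slc7a10 −5.45, Capn3 −4.18, Slc40a1 (the iron exporter ferroportin) −4.05 and Gata1 −4.02. The spread in this test includes the genotype difference, because each tissue held 1 library of each genotype. Without WT spleen 1909 genes were lower, without 2KR spleen 2178 were lower, and without 2KR eWAT 3403 were higher, each a change of more than 1.5 times.

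The second comparison asked how the fat Treg signature differed between genotypes, with 2KR eWAT set against WT eWAT. Fat Treg genes were lower in the 2KR library. Il1rl1 stood at 1431 CPM in WT eWAT and 278.5 CPM in 2KR eWAT, a log2 ratio of −2.36 (95% exact interval −2.42 to −2.30), and Areg at 2072 and 387.5 CPM, a log2 ratio of −2.42 (−2.47 to −2.37). Klrg1, a receptor of differentiated T cells, had −1.45, Gata3, a transcription factor of type 2 immunity, −1.26, Ccr2 −1.23 and Il10, an anti-inflammatory cytokine, −1.17. Cd36 did not share this pattern, with 154.6 CPM in WT eWAT and 157.3 CPM in 2KR eWAT and a log2 ratio of 0.02 (−0.08 to 0.13). Over the 36 known fat Treg genes the median was −0.97 in eWAT (95% order-statistic interval −1.17 to −0.24) and −0.07 in spleen. The eWAT median lay below all 10000 random lists matched on mean expression over the 4 libraries. Of the 36 genes 27 were below 0 in eWAT, and 17 were at −1 or lower against 1 at 1 or higher, Gpr55. These are descriptions of 2 libraries and no p-value was computed.

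Ccr7 was higher in 2KR eWAT, at 317 CPM in WT and 682 CPM in 2KR (log2 ratio 1.11, interval 1.05 to 1.17). The lymphoid or resting Treg list had a median of 0.28 (−0.31 to 0.75) with 17 of 24 genes above 0, and a percentile of 100 among matched random lists. Of its genes 4 were at 1 or higher, among them Ccr7 and Satb1 (1.22), and 2 at −1 or lower, Ccr9 (−1.61) and Ly6c1 (−1.13). Treg core genes had a median of −0.04 (−0.37 to 0.49, percentile 99.4). Within that list Foxp3 was at −0.53, Il2ra at −0.61 and Ctla4 at −0.37, while Lrrc32, which encodes the TGF-beta anchor GARP, was at 1.91 and Gpr83 at 1.17. The percentile compares a list with genes of like mean expression over the 4 libraries, not of like expression in eWAT. Ratios varied with level, from a median of −0.25 at 100 CPM or more to 0.70 in the lowest of 10 equal bins of level. Genes higher in eWAT are thus set against genes weaker there, which can move their percentile towards 0. Genes lower in eWAT can move towards 100. For lists that differ between tissues, a percentile near 0 or 100 is therefore not support by itself. The T cell identity median was −0.23 (−0.50 to −0.04, percentile 66.4) and became 0.02 under total count scaling, which shifts the median eWAT ratio of all genes by 0.25.

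Immediate early and stress genes, which cells switch on within minutes of stimulation, were also lower in 2KR eWAT. Their list had a median of −0.78 (−1.14 to −0.59) in eWAT, below every matched random list, and 0.08 in spleen, with 24 of 29 genes below 0. Atf3 was at 1176 CPM in WT eWAT and 258 CPM in 2KR eWAT, and Junb, an AP-1 subunit, at 7771 and 2859 CPM. NF-kB target genes had a median of −0.36 (−0.91 to 0.02, percentile 3), with an interval that included 0, Nfkbid at −1.15 and Cd83 at 0.99. PPARG target and lipid handling genes had a median of −0.26 (−0.42 to 0.02, percentile 4.65), and 20 of 30 genes were below 0. Hilpda was at −2.04, Plin2 at −1.56, Dgat1, a triglyceride synthesis enzyme, at −0.74 and Fabp4 at −0.60, whereas Pltp was at 0.74 and Abca1, a cholesterol exporter, at 1.05. Under total count scaling this median was −0.004. Cell cycle genes had a median of 0.42 (0.23 to 0.54, percentile 100) with 24 of 26 above 0, among them Cenpe at 0.88 and Ccnb2 at 0.77. Cytosolic ribosomal protein genes had a median of −0.41 (−0.49 to −0.27, percentile 0.18) in eWAT and −0.28 in spleen, and oxidative phosphorylation genes −0.33 (percentile 4.81) in eWAT and −0.29 in spleen. The medians in eWAT were −0.26 (percentile 21.1) for glycolysis genes and −0.22 (percentile 16.5) for cholesterol synthesis genes, each with an interval that included 0. They were 0.06 (percentile 99.3) for interferon response genes, 0.31 (percentile 99.9) for effector T helper genes and 0.001 (percentile 99.4) for chemokine and adhesion receptor genes, with intervals that included 0 but medians above nearly all matched random lists. The last list held members on both sides, with Cxcr6 at −2.52, Itgb7 at −1.06 and Cd44 at −1.01 against Ccr7.

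Markers of other cells also differed between these 2 fat libraries, in both directions. Dendritic cell and antigen presentation markers were higher in 2KR eWAT, with a median of 0.85 (0.56 to 1.16, percentile 100). So were B cell markers at 0.73 (0.43 to 1.18, percentile 99.9) and macrophage and monocyte markers at 0.50 (0.04 to 0.69, percentile 100). Endothelial markers had a median of 0.56 (0.10 to 1.19) at percentile 66.5 among lists of like mean expression over the 4 libraries. These markers were higher in eWAT, where the matching can move a percentile towards 0, so this percentile cannot decide. Fibroblast and mesothelial markers were lower, with a median of −0.88 (−1.29 to −0.53, percentile 0), 17 of 18 below 0 and Dcn, the matrix proteoglycan decorin, at 349 CPM in WT eWAT and 143 CPM in 2KR eWAT. Innate lymphoid type 2 and mast cell markers had a median of 0.98 (−0.71 to 5.10, percentile 98.1), with the mast cell genes Tpsb2 at 5.10, Cma1 at 3.69 and Fcer1a at 2.95 (6 and 52 reads). Of the innate lymphoid type 2 genes of that list, Calca was at −1.42 and Il5 at −0.71, while Arg1 at −0.26 (−0.67 to 0.14) and Hs3st1 at −0.16 (−0.65 to 0.32) had intervals that included 0. Below 0 were also Il1rl1, Areg, Gata3 and Klrg1, which those cells also express. Plasma cell markers had a median of 0.18 (−0.48 to 0.76, percentile 90.8) and CD8 T and NK cell markers of 0.06 (−0.40 to 0.81, percentile 55.5). The adipocyte median of 0.54 rested on 5 genes, the neutrophil median of −0.34 on 2 genes and the erythroid median of 1.09 on 2 genes.

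**Figure D2:**
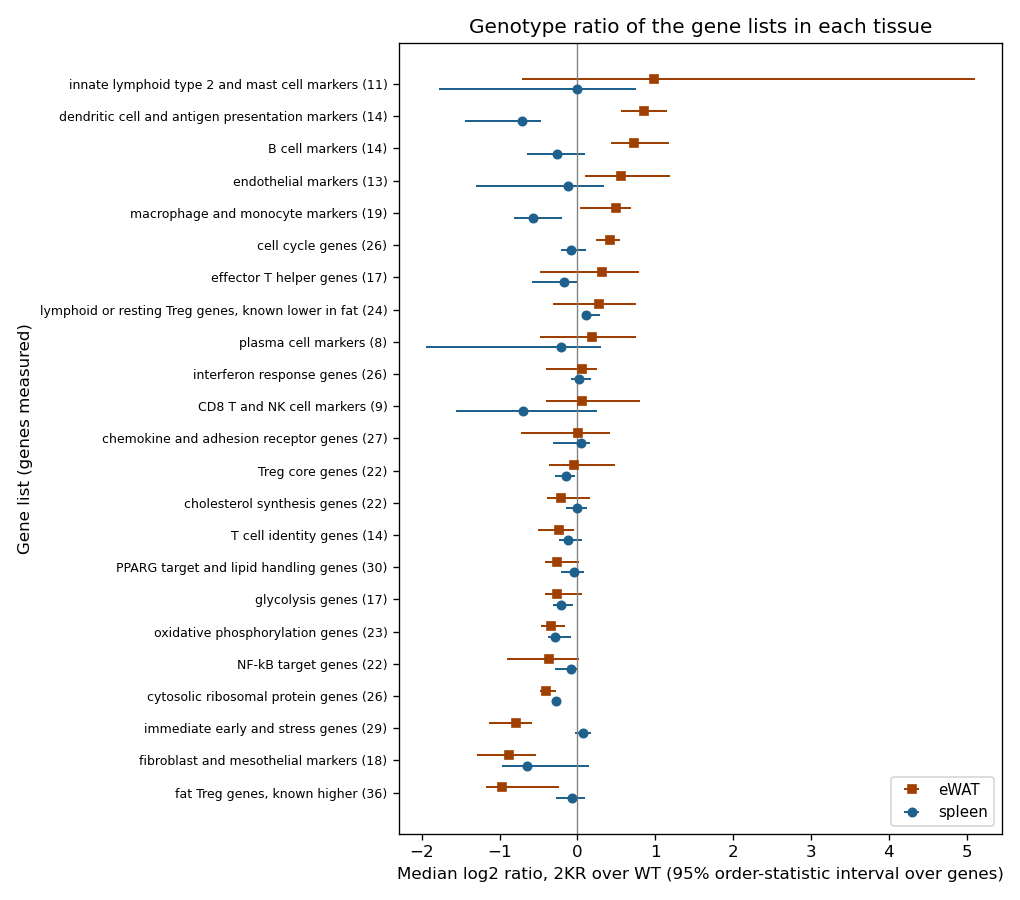
Median log2 ratio of 2KR over WT (horizontal axis) for the gene lists with at least 6 measured genes, in eWAT (squares) and spleen (circles), with 95% order-statistic intervals over genes, 1 library per group. Fat Treg genes lie at −0.97 in eWAT and −0.07 in spleen, and dendritic cell and antigen presentation markers lie at 0.85 in eWAT and −0.71 in spleen.

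Of 12364 genes at 5 CPM or more in at least 1 library, 682 had an eWAT log2 ratio of at least 1 and 287 of −1 or lower. Total count scaling gave 1309 and 135. Most of the higher genes were weakly expressed, and among the 7470 genes with a mean level of at least 20 CPM the counts were 38 and 131 (126 and 55 under total count scaling). Of those 131 lower genes, 72 had a mean tissue log2 ratio of at least 1, against 360 of the 7470 genes. Of the 38 higher genes, 22 had a mean tissue log2 ratio of −1 or lower, against 1019 of the 7470. The lowest ratios belonged to Bace2, an aspartyl protease (142.5 CPM in WT and 9.80 CPM in 2KR, log2 ratio −3.84, interval −4.18 to −3.56), Fam183b (−3.19), Slpi, a protease inhibitor (−3.18), Smad6 (−3.03), Pcsk1, a prohormone convertase (−2.97), Ccr1 (−2.80), Csf1, the macrophage growth factor (−2.58), the chemokine Cxcl2 (−2.55) and Mmp25 (−2.54). The highest ratios included genes of mast cells. Mcpt4, a mast cell protease, had 0 reads in WT eWAT and 102 in 2KR eWAT, at least 38.3-fold higher against a floor of 3 reads in the 1 library. Tpsb2, a mast cell tryptase, had 4 and 175 reads, Cma1 8 and 111, and Cpa3 22 and 155. Plag1 (2.52), Dgkg (2.23) and Lrig1 (1.98) followed. The lectin-like receptor genes Klrb1a (3.92) and Klra17 (3.19), and Vmn1r13 (1.97), belong to families of near-identical genes, so their counts are uncertain.

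In spleen, the control tissue, 2KR and WT Treg cells differed less among well expressed genes, with 5 at a log2 ratio of at least 1 and 9 at −1 or lower among the 7470. Over all 12364 genes the counts were 128 and 718, again mostly weakly expressed genes. Cyp4f18, a fatty acid hydroxylase, stood apart with 9 reads in WT spleen and 948 in 2KR spleen (log2 ratio 6.12, interval 5.49 to 7.55), while in eWAT it had 2557 reads in WT and 553 in 2KR (−2.03). Plxnd1 (1.60), Xrcc2 (1.45), Crebl2 (1.36) and Chic1 (1.36) were also higher in 2KR spleen. Beta-s, a beta-globin gene with near-identical copies (−2.79), Nek6 (−1.74), Hpgd, which degrades prostaglandins (−1.41), C1qa (−1.35) and Ecel1 (−1.29) were lower. Macrophage and monocyte markers had a spleen median of −0.57 (−0.82 to −0.20), and fibroblast and mesothelial markers of −0.64 (−0.97 to 0.15).

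The difference of the genotype ratios, eWAT minus spleen, set the genotype ratio in fat against that in spleen. A large value can come from either tissue. It was at least 1 for 1589 genes and −1 or lower for 370 (2019 and 200 under total count scaling), and it has no test because no residual degrees of freedom remain. Cyp4f18 had the lowest difference at −8.16, followed by Mmp25 at −3.85, Smad6 at −3.82 and Yes1, a SRC family kinase, at −3.10. In WT and 2KR spleen Mmp25 had 6 and 22 reads and Smad6 1 and 4 (spleen interval −1.64 to 7.32). The spleen part of these differences thus rested on few reads. Il1rl1 had −3.07. At the other end stood the mast cell genes and the myeloid receptor genes Tlr13 and Cd300ld, the latter at 4.70. Tlr13 had 27 reads in WT spleen and 0 in 2KR spleen, so its difference has no exact size. For Cyp4f18, Yes1 and Cd300ld the spleen ratio was the larger in size, at 6.12, 2.81 (1.90 to 5.27, from 4 and 50 reads) and −3.59 (−6.74 to −2.79, from 52 and 3 reads). Across genes, the tissue log2 ratios in WT and in 2KR had a Spearman rho of 0.868, where genes are not independent replicates.

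The 200 genes with the highest mean tissue ratio over both genotypes formed a fat-high signature and the 200 lowest a fat-low signature. Both were chosen on these libraries. The fat-high set was not limited to Treg genes. It began at a mean tissue log2 ratio of 4.70, and the myeloid lectin genes Clec10a and Mgl2 lay above that in both genotypes. How many of its genes belong to other cells was not counted, so its median does not describe Treg cells alone. The fat-low genes had a median genotype ratio of 0.41 (0.28 to 0.50, percentile 100) in eWAT, with 145 above 0, and −0.09 in spleen. The eWAT direction turned when all 3805 lower genes past the tissue threshold were taken, with a median of −0.19 (percentile 0), 1133 above 0 and 2672 below. The fat-high genes had a median of 0.03 (−0.20 to 0.24) in eWAT, with 101 above 0 and 99 below, which was below all matched random lists (percentile 0, but percentile 100 with a median of 0.37 when all 3034 genes past the tissue threshold were taken), and −0.42 in spleen, where most had few reads. Both signatures were also drawn from genes with a mean level of at least 50 CPM, a choice made after seeing the data. The fat-high median in eWAT was then −0.44 (−0.58 to −0.38), with 165 of 200 below 0 (percentile 0). The fat-low median was −0.07 (−0.13 to 0.05, percentile 100). Genes chosen for a tissue difference are matched poorly by mean level over both tissues, so the signature percentiles are not support for a genotype difference.

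A last test sought genotype differences shared by both tissues, with tissue as a term and 1 residual degree of freedom. It takes the 2 tissues of a genotype as its replicates. Whether both tissues came from the same animals is not known here. A difference between animals that both tissues share therefore cannot be told from one of genotype. The p-values do not cover spread between animals. The test found 11 genes lower in 2KR and 0 higher at an adjusted p under 0.05 (edgeR), with 565 lower and 212 higher at an unadjusted p under 0.05. DESeq2 gave 3 lower and 0 higher, and limma on log2(FPKM + 1) gave 2 lower and 2 higher. The 11 included receptors and ligands of chemokine signalling, Ccr1 (log2 fold change −2.49, SE 0.30, adjusted p = 0.000227), Ccr3 (−1.17), Cxcl1 (−1.86) and Cxcl3 (−1.84). The others were Pcsk1 (−2.74, SE 0.28, adjusted p = 1.41e-05), Bace2 (−2.67), Hpgd (−1.44), Slc41a3, a magnesium transporter (−1.24), Slco2b1 (−1.56), AA467197 (−3.29) and 1700061F12Rik (−2.03). Apart from AA467197, which had 2 reads in each spleen library and so no direction there, the 11 had lower values in 2KR in both tissues. In spleen Cxcl1 had 8 and 2 reads, Ccr1 14 and 10 and Slco2b1 12 and 11 (log2 ratio −0.36, interval −1.75 to 0.88). The spleen part of the calls for these genes thus rested on few reads, with spleen intervals that included 0. Pcsk1 had 24 and 9 reads there (interval −3.01 to −0.56). Among genes with a mean level under 20 CPM, 709 had a spleen ratio of −1 or lower and 123 of at least 1. In eWAT these counts were 156 and 644. Whether the spleen shift adds to the excess of lower genes in this test was not tested. Pparg (adjusted p = 0.0752) and Crebl2 (1.02, adjusted p = 0.0514) did not pass.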

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

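The tests of the 3 patterns weighed under this heading were chosen after the results were seen. The results below drew attention for differences in opposite directions in the 2 tissues, or for a signal in the transcript values that the comparisons did not use. Dendritic cell and antigen presentation markers had a median 2KR over WT log2 ratio of 0.85 in eWAT and −0.71 in spleen, a difference of 1.56. Il1rl1 had −2.36 in eWAT and 0.71 in spleen, a difference of −3.07. Neither difference was tested, because each group has 1 library. Genes in the lowest bin of level also moved apart, with medians of 0.70 in eWAT and −0.58 in spleen. Some dendritic cell markers had few reads in spleen, such as Cd209a with 14 in WT and 4 in 2KR. H2-Ab1 had 1340 and 1193 reads there, with log2 ratios of 0.83 in eWAT and −0.47 in spleen. Whether the dendritic cell list differs beyond this shift of weakly expressed genes was not tested. The Pparg transcript NM_011146 was at 26.1 FPKM in 2KR eWAT (95% bounds 22.8 to 29.5) and 0.97 FPKM in WT eWAT, while NM_001127330 was at 16.3 and 70.1 FPKM.

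The lower fat Treg genes in 2KR eWAT could come from the make-up of the sort. Fewer T cells would lower T cell identity genes as much, but the fat Treg median lay −0.74 from theirs (bootstrap interval over genes −0.97 to −0.01). This argues against fewer T cells alone, though narrowly, since genes of a list are not independent. A part stays open, because 13 of 14 T cell identity genes were below 0 (median −0.23, or 0.02 under total count scaling). Fibroblast markers (−0.88) and dendritic cell markers (0.85) moved apart, which cannot decide, since shares of other cells can change separately. Admixture of spleen-like Treg cells would leave the same share of the WT difference between eWAT and spleen in both Treg lists. Yet 0.42 (0.28 to 0.50) of it was left over 28 fat Treg genes and 0.92 (0.805 to 0.957) over 18 lymphoid genes. This argues against such admixture alone. The genes were those at a log2 of at least 1 between tissues in WT, in the list's known direction. Choosing them on WT can lower the share left in 2KR. Immediate early and stress genes were lower as well (−0.78), and these values cannot tell a difference in cell handling from a difference in cell state. A genotype effect on this list within eWAT stays open, with 1 library per genotype there, and a smaller share of innate lymphoid type 2 cells was not tested, with markers that differed in size (Calca −1.42, Il5 −0.71, Arg1 −0.26 and Hs3st1 −0.16, the last 2 with intervals that include 0).

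The many weakly expressed genes that were higher in 2KR eWAT may be background reads. Reads on 1451 olfactory and vomeronasal receptor genes, which T cells have little reason to express, were 2.41 times as frequent in 2KR eWAT as in WT eWAT (interval 2.34 to 2.49, reads taken as independent) and 0.57 times in 2KR spleen against WT spleen. This fits background in both tissues, since weakly expressed genes were lower in 2KR spleen. It does not rule out a genotype effect on some of these genes, which remains untested.

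The Pparg transcript split might reflect adipocyte RNA or the way shared reads were divided. Adipoq stood at 1.29 FPKM in 2KR eWAT against 26.1 FPKM for the transcript, which argues against adipocyte RNA. In spleen the share of Pparg FPKM given to NM_011146 was 100% in WT (71 reads) and 71.7% in 2KR (44 reads). The FPKM bounds of NM_001127330 did not overlap there (0 to 0.088 in WT and 0.104 to 0.760 in 2KR). Within WT the share went from 100% in spleen to 1.37% in eWAT. The division thus varied between libraries beyond the flagged contrast. With few reads in spleen, these values cannot tell an unstable division from a difference between the cells. A change of promoter use with genotype was not tested, because junction reads were not analysed here.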

How the results depend on the processing

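In eWAT the fat Treg median stayed below 0 (highest −0.711, under total count scaling) and the lymphoid or resting Treg median above 0 under every alternative. The PPARG target median stayed below 0 but reached −0.004 under total count scaling. The Treg core median, whose interval includes 0, went from −0.044 to 0.211 under total count scaling and 0.086 with FPKM. Where a value below differs from the report, the cause was not tested unless fewer genes or libraries enter by construction.

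Tissue effect: genes higher numbered 2727 with limma on log2(FPKM + 1), 2699 on log2(FPKM + 0.1) and 3076 without a filter, where 2303 were lower. Leaving out 1 library at a time gave 3403 to 5491 higher and 1909 to 5278 lower, with the lone library assumed to vary like the others. Common genotype effect, higher and lower: no low-count filter 9 and 42, limma on log2(FPKM + 1) 2 and 2, on log2(FPKM + 0.1) 2 and 3, and without a filter 2 and 4. RLE factors gave 1 higher and DESeq2 3 lower.

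Genotype in eWAT, genes at log2 of 1 or more and of −1 or less: total count scaling 1309 and 135, centring on genes of at least 100 CPM 1304 and 134, CPM filter of 1 2378 and 456, CPM filter of 20 100 and 200 (33.3% higher against 70.4% in the report, so the majority turned), median-centred FPKM 227 and 176, size threshold of 1.5-fold 1851 and 1237 and of 4-fold 39 and 27, mean level of at least 20 CPM 38 and 131. At that level the majority turned with scaling, to 126 and 55 under total counts and 123 and 55 under centring. Spleen: prior count of 8 41 and 333, CPM filter of 1 435 and 2091, CPM filter of 20 26 and 95, FPKM 9 and 33, mean level of at least 20 CPM 5 and 9. Difference between tissues: total count scaling 2019 and 200, CPM filter of 1 4481 and 636, CPM filter of 20 276 and 261 (51.4% higher against 81.1%), FPKM 451 and 234.

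The T cell identity median in eWAT turned from −0.231 to 0.024 under total count scaling and 0.019 under centring. Ctla4 in spleen turned to 0.007 under FPKM. The fat-high signature in eWAT was 0.28 under total count scaling, 0.276 under centring, 0.273 with 500 genes, 0.371 with all genes past the threshold, where its percentile turned from 0 to 100, and −0.44 at 50 CPM or more. In spleen it was −0.717 with a prior count of 0.5, −0.064 with FPKM and −0.019 at 50 CPM or more. The fat-low signature in eWAT was 0.667 under total count scaling, 0.663 under centring, 0.656 with 100 genes and 0.089 with 500 genes, and it turned to −0.187 with all genes past the threshold (percentile 0) and −0.068 at 50 CPM or more (percentile 100).

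Among other values, 397 of 407 tissue effects of named genes kept their call, 4 were stronger and 6 weaker. Of 555 genotype ratios of named genes 470 were the same, 84 moved and 1 turned. Of 60 common genotype values 24 were the same, 34 weaker and 2 stronger. Of 153 further list medians for genotype 138 were the same, 13 moved and 2 turned, and of 88 tissue values of lists 84 were the same and 4 moved. The tissue test with genotype as an additive term, which pairs the libraries by genotype, gave 4487 genes higher and 4007 lower. Depth limits a gene with 0 reads to 0.242 CPM in WT spleen and 0.313 CPM in 2KR eWAT.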

Other observations

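Pparg is read from more than 1 promoter, and its 2 transcripts in these files differ at the start of the protein. The deposited FPKM values assign 1.37% of Pparg to NM_011146 in WT eWAT and 61.5% in 2KR eWAT, and whether this holds for the cells depends on how shared reads were divided, which was not settled here. Foxp3 was assigned mostly to NM_054039 in every library, at 398, 376, 363 and 289 FPKM in WT spleen, 2KR spleen, WT eWAT and 2KR eWAT.

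The test of the region around Pparg was written before its result was seen. Unreplaced chromosome 6 sequence beside an edited gene could add genotype differences to both tissues. Among 100 tested genes around Pparg (105627739 to 120772703 in mm9), 9 had an unadjusted p under 0.05, which put this window at percentile 92.4 of 14477 windows, with a median of 4 and a 95th percentile of 10. The 9 include Pparg itself. By the rule written in advance, a percentile under 95 counts against this explanation. The count has a Poisson interval of 4.1 to 17.1, which reaches past the 95th percentile of 10. This interval was not part of that rule, and with it the test cannot tell. Genes named above for genotype that also lie on chromosome 6 included Slc41a3, Lrig1, Klrb1a, Klra17, Vmn1r13, Plxnd1 and Crebl2. Of these only Plxnd1 (start 115904829) lies inside the window, while most other genes named for genotype lie on other chromosomes. Whether genotype differences gather elsewhere on chromosome 6 was not tested.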
